A study of Mus musculus with 24 samples.

How the data were processed

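RNA was measured by bulk sequencing in mouse placenta at embryonic day 13, per the labels, from fetuses of control dams and of dams restrained under bright light 3 times a day for 45 minutes until that day. The 24 libraries fell into 4 groups of 6, namely female control, female stress, male control and male stress. RNA was isolated with a Qiagen RNA Mini Kit and libraries were made with NEBNext Ultra II, per the labels. The submitters' processing notes name Trim Galore 0.5.0, Salmon 1.10.1, DESeq2 1.34.0 and the genome build mm10, with no role or order for any of them.

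The deposited count table held expected counts from the authors' quantification, as whole numbers per gene, with no normalization. It listed 17790 genes, each with a total of at least 10 counts over the libraries. The deposited table of TPM (abundance per transcript, scaled to the same sum in each library), made by the authors, gave 1 value per transcript for 116546 transcripts. The gene annotation release was not given in the sources used here. Symbols, positions and gene types came from GENCODE M21 on GRCm38, which matched 17704 of the genes (99.5%) and 115898 of the transcripts.

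Groups came from the labels of sex and treatment. Library names carry 13 prefixes, 7 in control and 6 in stress libraries, and 11 of the prefixes hold both sexes. The labels do not say what a prefix or a replicate number stands for, nor whether libraries come from separate dams or litters. The p-values therefore measure the spread among these libraries, and libraries that share a prefix may share a source.

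Before the data were examined, the comparisons, the tests, the gene lists, the rule for named genes and the other settings to be tried were fixed. Counts were analysed in R 4.3.3 with edgeR 4.0.16. The steps were the filterByExpr filter by group, which left 14848 genes, TMM factors, estimateDisp, glmQLFit with robust estimation and glmQLFTest, with 1 mean per group over all 24 libraries. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Group values are given as CPM (counts scaled by the TMM library size) with the standard deviation (SD) over 6 libraries. The common biological coefficient of variation was 26.4%.

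Comparisons were the stress effect in females, the stress effect in males, the difference of these effects (females minus males), the stress effect averaged over the sexes, and the sex difference (female minus male) in controls and under stress. Of 33 gene lists fixed beforehand, 32 were tested in each comparison with camera at a preset correlation of 0.01, two-sided, and adjusted by Benjamini-Hochberg over the lists. A list needed 3 tested members, and the list of Y-linked genes had none. Camera compares a list with the other genes, so a list can rank high although its members are low. Each list test was repeated with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. Genes of a list can vary together, so a count of its members is not a count of independent observations. A list score was the mean log2 CPM of its genes in a library, and scores of 6 lists of other cell types were compared between stress and control within each sex by an exact permutation test over all 924 splits, two-sided.

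Named genes followed this rule. The 8 higher and 8 lower called genes with the smallest p were named where their mean was at least 1 CPM and their symbol was not a clone, pseudogene or identifier. For each list with an adjusted camera p under 0.05, the 4 members with the smallest p were named. In the stress comparisons 12 fixed genes of stress hormone, serotonin, growth and transport biology were always given. Where under 3 genes were called in a direction, the 5 with the smallest p were given as values only. Parts of the rule were summarised as a count and a range, and a gene outside it is said to have been chosen after its values were seen.

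The gene test was tested on simulated data in which 200 of 14848 genes had a known change. At a 2-fold change it recovered 79.1% of the genes in either within-sex stress comparison, 70.1% for the difference between sexes (where 1 sex alone changed), and 83.6% and 80.6% for the sex differences in controls and under stress. Between 1 and 11 unchanged genes were called in a comparison. At a 1.5-fold change 62.7% of the genes were recovered in females and 71.6% in males. A simulated list of 20 genes moved together was called, and 0 of the other 31 lists were. The changed genes were taken only from those with an average above 1 CPM, so the rates of recovery do not cover lower genes. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often a list whose genes vary together is called falsely. Random splits of the libraries, added after the results were seen, called a median of 7 to 11 lists, depending on the comparison. The real groupings called 11 to 13. A list call at the preset correlation was thus common under random grouping too.

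The settings tried beside it were relative log expression and upper-quartile factors, no filter and a stricter filter of 1 CPM in 6 libraries, DESeq2 1.42.0, voom with quality weights in limma 3.58.1, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), 1 surrogate variable from sva 3.50.0, the maternal decidua score as a covariate, only the 2 groups compared, the replicate number or the library-name prefix as a block, counts summed or correlated by prefix, and leaving out each library in turn. Added after seeing the data were the yolk sac score as a covariate, both scores as covariates, the number in the prefix as a covariate, leaving out the 3 libraries with the lowest decidua score, leaving out the 4 control libraries with over 30 M counts (M is the prefix mega), and leaving out single libraries in the list tests. The genes of the Y-linked list were read from the TPM table, as a check of the sex labels, and Xist was not analysed here.

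Total counts ran from 18.3 to 43.03 M per library. The filter, the prior counts of the fit and the depth of the smallest library limit what can be said of genes near 1 CPM. Values of genes with close copies, such as Rps27, Oas1a, the Prl, Psg and Ceacam families and mitochondrially encoded genes, carry an uncertainty from reads that fit more than 1 place, which was not measured.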

Results

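Gene expression was measured by RNA sequencing in 24 mouse placentas collected at embryonic day 13. They came from 4 groups of 6, female and male fetuses of control dams and female and male fetuses of dams under repeated restraint. Restraint means confinement that prevents movement, here under bright light 3 times a day for 45 minutes. Median depth was 23.3 M counts (M is the prefix mega) in female controls (20.3 to 40.7), 21.7 in stressed females (19.6 to 27.0), 22.1 in male controls (18.3 to 43.03) and 22.9 in stressed males (19.5 to 42.8). The 5 libraries over 30 M were replicates 1 and 2 of both control groups and replicate 2 of the stressed males. Mitochondrially encoded genes took 1.78% to 3.03% of the counts.

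Levels of yolk sac and maternal tissue markers differed widely between the libraries. Afp, a serum protein of the yolk sac endoderm, ran from 5.20 to 16490 CPM over the 24 libraries, with a median of 1327 CPM. Apoa1, an apolipoprotein of the same tissue, ran from 0.955 to 2093 CPM, and Ttr, a thyroid hormone carrier, from 1.03 to 597.6 CPM. On the maternal side, Prl8a2, a prolactin family hormone of the decidua, ran from 86.8 to 2019.8 CPM. Gzmc, a granzyme of uterine natural killer cells, ran from 13.7 to 260.2 CPM. The score of the decidua list, its mean log2 CPM, was lowest in female stress replicates 4 and 5 (3.81 and 4.12) and in female control replicate 3 (4.63). Scores of 6 lists were compared between stress and control in each sex by exact permutation tests. In females the neutrophil score differed by -0.82 (exact p = 0.0390, n = 6 per group), the macrophage score by -0.61 (exact p = 0.0779) and the decidua score by -0.65 (exact p = 0.0996). After adjustment over the 12 tests the smallest of these exact p-values was 0.398, so 0 scores passed. In males the decidua score differed by 0.19 (exact p = 0.216) and the red cell score by 0.20 (exact p = 0.203). Yolk sac scores differed by 0.77 in females (exact p = 0.545) and -0.92 in males (exact p = 0.504), each less than the spread between replicates, and uterine natural killer cell scores by -0.31 and 0.21 (exact p = 0.636 and 0.489).

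**Figure D1:**
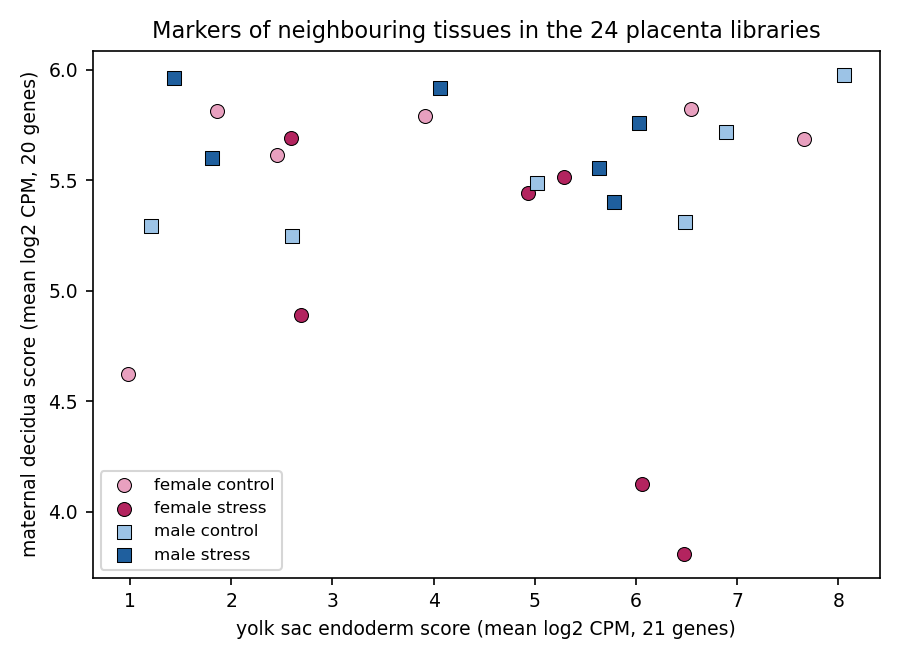
Score of the maternal decidua list (mean log2 CPM of 20 genes, vertical axis) against that of the yolk sac endoderm list (21 genes, horizontal axis), with 1 point per library and symbols for the 4 groups of 6. Female stress replicates 4 and 5 lay lowest in decidua score (3.81 and 4.12), and the yolk sac score spread widely within each group.

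The effect of maternal restraint on the placentas of female fetuses was asked first. Markers of the maternal decidua, the uterine tissue on the maternal side, were lower as a group in stressed than in control females, with 17 of 20 genes lower and a median log2 fold change of -0.53. Cryab, a small heat shock protein, had means of 180 ± 55.6 CPM (SD, n = 6) in control and 80.0 ± 39.9 in stressed females, a log2 fold change of -1.17 ± 0.32 (SE). Angpt4, an angiopoietin, had -1.16 ± 0.34 and Esr1, an estrogen receptor, -0.80 ± 0.30. The camera adjusted p of the decidua list was 7.16e-07 with the preset correlation and 0.378 with an estimated correlation. None of its genes passed over all genes, and 3 lower genes passed when adjusted over the list alone. The call ended with its own score as a covariate (0.964), and with both tissue scores, of decidua and yolk sac, as covariates (0.808).

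Immune gene groups were lower in the same female libraries, in which the decidua score was also lower (5.56 against 4.91). Interferon response genes were lower in 20 of 21 cases (adjusted p = 4.98e-06), among them Oas1a, a sensor of double-stranded RNA (-0.36 ± 0.09), and Ifit2 (-1.15 ± 0.43). Macrophage markers were lower in 15 of 17 cases with a median of -0.71 (adjusted p = 0.000146). Examples were Tyrobp, a signalling adaptor of myeloid cells (-0.99 ± 0.35), and Cd14, a coreceptor for bacterial lipopolysaccharide (-0.89 ± 0.36). Inflammatory cytokines and chemokines were lower in 14 of 17 cases (adjusted p = 0.00163), with Ccl2, which draws monocytes, at -1.81 ± 0.54. Neutrophil markers were lower in 8 of 11 cases (adjusted p = 0.00977), with Ltf, an iron-binding protein of neutrophil granules, at -1.98 ± 0.69. The adjusted p with an estimated correlation was 0.378 for the interferon, cytokine and neutrophil lists and 0.440 for the macrophage list. Over all genes 0 members of these 4 lists passed, and adjusted over the list alone 1 interferon gene (Oas1a) and 3 cytokine genes passed, all lower. Uterine natural killer cell markers were lower in 11 of 12 cases without passing (adjusted p = 0.0655). The antioxidant list was lower in 16 of 19 cases (adjusted p = 0.00578, and 0.378 with an estimated correlation), with Prdx1, a peroxidase, at -0.20 ± 0.07. The cytokine call ended with the decidua score as a covariate (adjusted p = 0.231) or both tissue scores (0.210), while the interferon and macrophage calls stayed in 9 of 9 other settings at the preset correlation, these among them, and without each of 12 libraries. The neutrophil call ended with both tissue scores (0.0541), without the 3 low-decidua libraries (0.116), without the 4 deep control libraries (0.190), and without female control replicate 1 (0.0731) or female stress replicate 5 (0.0636). The antioxidant call ended without female control replicate 2 (0.0509).

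Of the 4 trophoblast lists 2 ranked higher in the stressed females, those of syncytiotrophoblast and giant cells, while spongiotrophoblast and glycogen cells (13 of 22 higher, adjusted p = 0.329) and labyrinth progenitors (6 of 13 higher, 0.998) were not called. Labyrinth syncytiotrophoblast markers, of the cell layer where maternal and fetal blood exchange nutrients, were higher in 18 of 20 cases (median 0.20). Syna (ENSMUSG00000085957, chromosome 5, 134558146 to 134560171 on GRCm38, protein-coding), the envelope-derived protein that fuses these cells, had means of 143 ± 18.6 CPM in control and 215 ± 17.9 in stressed females (SD, n = 6). Its log2 fold change was 0.59 ± 0.14 (SE), and the 6 stressed libraries (189.7 to 239.6 CPM) lay above the 6 controls (120.4 to 171.2 CPM). The list had an adjusted p of 1.95e-05, and 0.400 with an estimated correlation. Syna alone passed when adjusted over the list alone. Imprinted genes were higher in 22 of 31 cases (adjusted p = 0.00193, and 0.378 with an estimated correlation), with a median of 0.14 and a mean of 0.01. Igf2, a fetal growth factor, had means of 2725 ± 232 and 3057 ± 147 CPM (log2 fold change 0.17 ± 0.06), and Plagl1, a zinc finger regulator of growth, 0.35 ± 0.13. Trophoblast giant cell markers were higher in 16 of 17 cases (adjusted p = 0.00381), with Ctsj, a placental cathepsin, at 0.28 ± 0.15, and cell cycle genes in 24 of 25 (0.000428), with Aurkb, a mitotic kinase, at 0.26 ± 0.15. Mitochondrially encoded genes were higher in 12 of 13 cases (0.00706), with mt-Nd3 at 0.73 ± 0.29. These 3 lists had an adjusted p with an estimated correlation of 0.649, 0.685 and 0.652, and 0 of their genes passed by either count. Heat shock chaperones had an adjusted p of 0.0480, and 0.685 with an estimated correlation. Dnajb1, a cochaperone, had 0.23 ± 0.08, while Cryab was the 1 member that passed when adjusted over the list alone, and it was lower. After the results were seen, camera p-values were set against 100 splits with stress labels moved at random among female libraries, the real grouping included. Values as small came up in 47 splits for cell cycle, 25 for giant cell, 24 for mitochondrial and 24 for heat shock genes. They came up in 14 splits for syncytiotrophoblast and 3 for imprinted genes. Leaving out female control replicate 1 ended the cell cycle call (0.161) and the mitochondrial call (0.172), as did female stress replicate 6 for the latter (0.0743). The heat shock call ended (0.0717 to 0.280) without any 1 of female control replicates 2, 4 and 6 and female stress replicates 1, 3, 5 and 6. Other settings that ended calls were the decidua score and both tissue scores for cell cycle (0.148 and 0.328) and heat shock genes (0.241 and 0.101), the prefix number for heat shock genes (0.105), and the loss of the 4 deep control libraries for mitochondrial (0.116) and heat shock genes (0.0832).

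Among single genes, edgeR called 0 of 14848 in females (smallest adjusted p 0.445), with 1362 at an unadjusted p under 0.05 (520 higher, 842 lower) against 742.4 for chance. DESeq2, run without the edgeR filter on 17784 genes, called 12. Of these 2 were higher (Syna, adjusted p 0.0402, and Acad10, 0.0490) and 10 lower, among them Rps27, Cyb5r1, Fggy and Poglut1. The higher genes with the smallest edgeR p were Acad10 (0.51 ± 0.12), Syna, Tbc1d14 (0.26 ± 0.06), Pla2g6 (0.19 ± 0.05) and Slc12a7 (0.37 ± 0.10). The lower ones were Cyb5r1, a reductase (-0.51 ± 0.10), Rps27, a ribosomal protein gene with many copies (-1.37 ± 0.28), Zfp994 (-0.69 ± 0.15), Poglut1, a glycosyltransferase of Notch (-0.30 ± 0.07), and Fggy (-1.32 ± 0.29). Stress hormone genes moved by less than their error allows to tell from 0. Hsd11b2, which inactivates glucocorticoids in the placenta, had 0.07 ± 0.15, the glucocorticoid receptor Nr3c1 -0.03 ± 0.07 and its cochaperone Fkbp5 0.06 ± 0.10. The glucocorticoid response list had an adjusted p of 0.114, with 16 of 21 genes lower. The other fixed genes lay between -0.39 ± 0.27 (the serotonin transporter Slc6a4) and 0.20 ± 0.83 (Tph1, of serotonin synthesis). Yolk sac markers were lower in 21 of 21 cases with a median of -0.53, while camera placed the list upward (0.405) and its mean log2 score was higher by 0.77.

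The next comparison asked what restraint did in the placentas of male fetuses. Glucocorticoid response genes were higher as a group in stressed males, in 19 of 21 cases with a median of 0.23. Zbtb16, a transcription factor induced by glucocorticoids, had means of 3.23 ± 1.65 CPM in control and 6.58 ± 0.803 in stressed males (SD, n = 6), a log2 fold change of 1.02 ± 0.39. Errfi1, a feedback inhibitor of EGF receptor signalling, had means of 214 ± 45.6 and 306 ± 54.9 CPM (0.52 ± 0.19), and the clock gene Per1 had 0.23 ± 0.07. This list had an adjusted p of 3.06e-05, and 0.692 with an estimated correlation. Syncytiotrophoblast markers were higher in 20 of 20 cases (median 0.18, adjusted p = 1.93e-06, and 0.692 with an estimated correlation). Examples were Syna (0.39 ± 0.14), Stra6, a vitamin A receptor (0.34 ± 0.12), and the transferrin receptor Tfrc (0.53 ± 0.22).

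Other groups moved less firmly in males. Endothelial markers were higher in 17 of 17 cases (adjusted p = 0.000757), with Emcn, an endothelial mucin, at 0.30 ± 0.14. Imprinted genes were higher in 20 of 31 cases (0.0394), with Rtl1, needed for placental capillaries, at 0.41 ± 0.14, and had a median of 0.07 against a mean of -0.01. Glucose and lipid transport genes were higher in 17 of 21 cases (0.0394, Lipg 0.22 ± 0.08), immediate early genes in 13 of 17 (0.0352, Klf2 0.37 ± 0.15), red cell markers in 17 of 18 (0.0298, Tmcc2 0.36 ± 0.16) and decidua markers in 14 of 20 (0.0373, Bmp2 0.35 ± 0.14). Lower as groups were nuclear-encoded oxidative phosphorylation genes, in 26 of 27 cases (0.00154, Ndufs4 -0.21 ± 0.08), and spongiotrophoblast and glycogen cell markers, in 16 of 22 (0.0103). Of the latter, Aldh1a3, which makes retinoic acid, had means of 140 ± 40.1 and 82.8 ± 18.8 CPM (-0.76 ± 0.26). Yolk sac markers were lower in 21 of 21 cases (0.00224, median -1.47), with Dab2, an endocytic adaptor, at -0.70 ± 0.39. These genes varied together (estimated correlation 0.946), and the yolk sac score of the libraries differed by -0.92 (exact permutation p = 0.504). With an estimated correlation the adjusted p of these 9 lists was 0.692 to 0.701, and 0 genes of the 11 called lists passed, over all genes or adjusted over the list alone. With stress labels moved at random among the male libraries, a camera p as small came up in 10 to 47 of 100 splits for these 9 lists. The real grouping was included, and the 47 splits were those of yolk sac markers. Calls that did not survive the loss of 1 library were those of yolk sac (male control replicate 1, 0.292, and stress replicate 6, 0.0545), oxidative phosphorylation (control replicate 2, 0.183), spongiotrophoblast (control replicate 6, 0.0810), glucose and lipid transport (control replicates 1, 5 and 6 and stress replicates 4 and 5, 0.0647 to 0.111) and immediate early genes (control replicates 1, 3, 4 and 6 and stress replicate 2, 0.0576 to 0.333). So it was for imprinted genes (control replicates 2 and 6 and stress replicates 3, 4 and 6, 0.0638 to 0.256), red cell markers (control replicates 1, 2 and 6 and stress replicates 1 and 6, 0.0589 to 0.242) and decidua markers (control replicates 2, 3, 4 and 6 and stress replicates 1, 2 and 5, 0.0526 to 0.148), and leaving out the 4 deep control libraries ended the endothelial (0.0511), red cell (0.407) and imprinted calls (0.244). Further calls ended with the decidua score or both tissue scores for immediate early (0.178 and 0.194) and decidua markers (0.480 and 0.456), with the yolk sac score or both for yolk sac markers (0.799 and 0.771), and with the yolk sac score for glucose and lipid transport (0.0541). The prefix number ended calls for that list (0.0552) and imprinted genes (0.0684).

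Across single genes in males edgeR called 0 (smallest adjusted p 0.617), with 1150 at an unadjusted p under 0.05 (541 higher, 609 lower). DESeq2 called 8, of which Foxj3, Fam117b, Tdrd1 and Ankrd23 were higher, and Rps3a2, Rps3a3, Rpl17-ps5 and Sprr2a3, named after their values were seen and members of families with close copies, were lower. The values of the higher genes with the smallest edgeR p were 0.22 ± 0.05 for Foxj3, 0.39 ± 0.08 for Fam117b, 0.62 ± 0.14 for Ankrd23, a muscle ankyrin repeat protein, 0.86 ± 0.20 for Tdrd1, and 0.24 ± 0.06 for the X-linked histone demethylase Kdm6a, which alone passed when adjusted over its list alone. Lower were Sdhd, a subunit of respiratory complex II (-0.22 ± 0.05), C1ql1 (-1.503 ± 0.374), Lcp1, a leukocyte actin-bundling protein (-0.44 ± 0.11), Tmem106a (-0.27 ± 0.07) and Lrrc15 (-1.20 ± 0.32). Hsd11b1, which regenerates active glucocorticoid and is itself in the glucocorticoid list, had means of 43.9 ± 20.7 and 76.7 ± 28.2 CPM (0.81 ± 0.44, adjusted p = 0.654). The other fixed genes lay between -1.41 ± 0.85 (Tph1) and 0.20 ± 0.15 (Hsd11b2).

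The series title speaks of sex-specific change, so the difference of the stress effect was tested itself, as the effect in females minus that in males. Decidua markers had the list difference with the smallest camera p, lower in females in 18 of 20 cases with a median of -0.69. Esr1 differed by -1.06 ± 0.43 (SE, n = 6 per group), Cryab by -1.03 ± 0.45 and Il11ra1, a receptor for interleukin 11 in decidual growth, by -0.45 ± 0.18. Glucocorticoid response genes differed downward in 19 of 21 cases, with a median of -0.21. Sgk1, a salt-handling kinase, had means of 184 ± 51.0 and 144 ± 66.8 CPM in control and stressed females and 173 ± 33.7 and 238 ± 36.1 in males, a difference of -0.82 ± 0.37. Zbtb16 differed by -1.08 ± 0.54 and Errfi1 by -0.64 ± 0.27. The adjusted p was 1.35e-09 for decidua and 2.99e-06 for glucocorticoid genes, and 0.473 for both with an estimated correlation. With the decidua score as a covariate the decidua (0.480) and glucocorticoid calls (0.0567) ended, and with both tissue scores the decidua call did (0.445).

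Giant cell markers differed upward in 15 of 17 cases (adjusted p = 0.000345, Ctsj 0.41 ± 0.21), spongiotrophoblast and glycogen cell markers in 18 of 22 (0.00350, Igfbp7 0.28 ± 0.16), yolk sac markers in 21 of 21 (0.00162, Dab2 0.46 ± 0.55), cell cycle genes in 23 of 25 (0.00541, though Rrm2, of nucleotide synthesis, had -1.05 ± 0.53) and heat shock chaperones in 12 of 14 (0.0368, though Cryab was lower). Neutrophil markers differed downward in 9 of 11 cases (0.0213, Ltf -2.44 ± 0.95), endothelial markers in 14 of 17 (0.0213), interferon genes in 17 of 21 (0.0236, Oas1a -0.28 ± 0.13) and angiogenic factors in 14 of 20 (0.0237). Of the endothelial and angiogenic genes, the VEGF receptor Kdr, which both lists hold, had -0.40 ± 0.19. These 9 lists lay at an adjusted p of 0.714 to 0.757 with an estimated correlation, and in the 11 called lists 0 genes passed over all genes or adjusted over the list alone. Syncytiotrophoblast markers gave no sign of a difference (9 of 20 higher, adjusted p = 0.897). Calls that ended without single libraries were yolk sac (male control replicate 1, 0.140), cell cycle (female control replicate 1, 0.269, and male stress replicate 2, 0.0674), neutrophil (female control replicates 1 and 2, female stress replicate 5 and male control replicates 1 and 4, 0.0533 to 0.0915) and endothelial genes (female control replicates 4 and 5, male control replicate 1 and male stress replicate 5, 0.0667 to 0.114). The same held for interferon genes (female control replicate 4, female stress replicates 3 and 5, male control replicates 1 and 4 and male stress replicate 5, 0.0724 to 0.205), angiogenic factors (female control replicates 2, 4, 5 and 6, male control replicate 2 and male stress replicate 5, 0.0563 to 0.0720) and heat shock genes (female control replicates 2, 4 and 6, female stress replicates 1, 3, 5 and 6, male control replicates 1, 4 and 6 and male stress replicates 1 and 2, 0.0526 to 0.147). Calls also ended with the decidua score for cell cycle (0.637), heat shock (0.160), neutrophil (0.120), endothelial (0.201), interferon (0.696) and angiogenic genes (0.749). Both tissue scores ended those of yolk sac (0.894), cell cycle (0.894), neutrophil (0.252), endothelial (0.444), interferon (0.967) and angiogenic genes (0.947). The yolk sac score ended those of yolk sac (0.738), neutrophil (0.0555), endothelial (0.0679) and interferon genes (0.0755). Without the 3 low-decidua libraries the yolk sac (0.904) and neutrophil calls (0.0785) ended. That of heat shock genes ended without the 4 deep control libraries (0.1001) or with the prefix number (0.0554).

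At the level of genes edgeR called 0 for the difference (smallest adjusted p 0.909), with 635 at an unadjusted p under 0.05, fewer than the 742.4 of chance. DESeq2 called 1, Rps27, whose means were 16.9 ± 8.17 and 6.50 ± 2.11 CPM in control and stressed females and 9.74 ± 1.76 and 13.7 ± 4.66 in males (edgeR difference -1.86 ± 0.40). Other values with the smallest p were those of Rbp1, a retinol-binding protein (0.40 ± 0.10), Brd3os (0.80 ± 0.24), Gtf2h2 (0.43 ± 0.13), Cyp17a1, of androgen synthesis (0.57 ± 0.18), and Bcl7c (0.31 ± 0.10) upward, and of Poglut1 (-0.37 ± 0.09), Bbs12 (-1.09 ± 0.30), Plekha1 (-0.74 ± 0.20) and Atp10b (-1.28 ± 0.36) downward. The fixed genes lay between -1.10 ± 0.63 (Hsd11b1) and 1.61 ± 1.19 (Tph1), with Igf2 at 0.20 ± 0.09.

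Averaged over the sexes, stress went with higher syncytiotrophoblast markers, in 19 of 20 cases with a median of 0.18. Syna had 0.49 ± 0.10 (SE, n = 6 in each of 4 groups), Stra6 0.30 ± 0.09, the gap junction protein Gjb2 0.27 ± 0.09 and the lactate transporter Slc16a1 0.23 ± 0.08. Adjusted over the list alone 8 of the 20 passed, all higher, and over all genes 0 did. The list had an adjusted p of 2.14e-09, and 0.368 with an estimated correlation. Without the 4 deep control libraries its mean score differed by 0.11 (95% interval -0.02 to 0.23) in place of 0.20 (0.06 to 0.34). Amino acid transporters were called upward (adjusted p = 0.0152, and 0.420 with an estimated correlation) with a median of 0.12 and a mean of -0.06, and 7 higher and 3 lower genes passed when adjusted over the list alone. Slc7a5 and Slc3a2, which form a carrier of large neutral amino acids, had 0.35 ± 0.10 and 0.13 ± 0.04, and the glutamine carrier Slc1a5 0.34 ± 0.11. Imprinted genes were higher in 22 of 31 cases (0.000838, and 0.368 with an estimated correlation), and Plagl1 (0.33 ± 0.09) and Rtl1 (0.34 ± 0.10) passed when adjusted over the list alone.

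**Figure D2:**
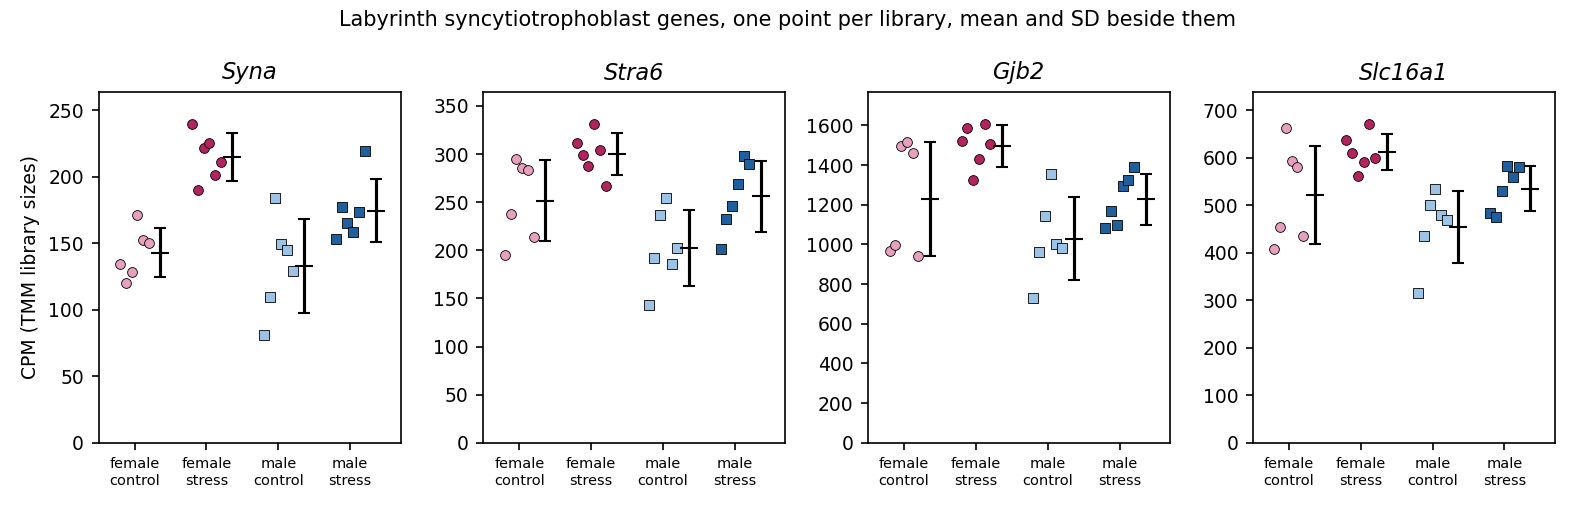
CPM (vertical axis) of Syna, Stra6, Gjb2 and Slc16a1 in each library, by group, with bars at the mean and SD of 6 libraries. For Syna the group means were 143 and 215 CPM in control and stressed females and 133 and 174 CPM in control and stressed males.

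Of the immune lists 3 were lower on average, while those of neutrophils (8 of 11 lower, adjusted p = 0.152) and uterine natural killer cells (12 of 12 lower, 0.396) were not called. Interferon genes were lower in 18 of 21 cases (adjusted p = 6.75e-05), with Oas1a (-0.22 ± 0.06) and Irf7 (-0.25 ± 0.08) past the threshold when adjusted over the list alone. Macrophage markers were lower in 15 of 17 cases (0.000266, Tyrobp -0.66 ± 0.25) and cytokine genes in 15 of 17 (0.00141), where Ccl2 (-1.27 ± 0.37) passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.420, 0.496 and 0.420. Oxidative phosphorylation genes were lower in 23 of 27 cases (0.00108, and 0.755 with an estimated correlation), with Cox7a2 at -0.13 ± 0.04, and antioxidant genes in 17 of 19 (0.0265, and 0.496). Endothelial (0.0265), cell cycle (0.0265) and glucose and lipid transport genes (0.0489) were called upward, with estimated-correlation adjusted p of 0.755, 0.844 and 0.496. Without the 4 deep control libraries the cytokine (0.0592), amino acid (0.0592), antioxidant (0.248), endothelial (0.990), cell cycle (0.990) and transport (0.196) calls ended, and the following ended without single libraries. They were the calls of antioxidant (female control replicate 2 and male control replicates 1 and 2, 0.0617 to 0.0666) and endothelial (female control replicates 1 and 3, female stress replicate 6, male control replicates 1 and 2 and male stress replicate 5, 0.0554 to 0.164). Added to these were the calls of cell cycle (female control replicates 1 and 6, female stress replicate 1, male control replicates 1, 2 and 4 and male stress replicates 1, 3 and 4, 0.0501 to 0.336) and transport genes (female control replicates 1, 3 and 6, female stress replicates 1, 5 and 6, male control replicates 1, 5 and 6 and male stress replicates 4 and 5, 0.0574 to 0.142). Without the 3 low-decidua libraries the amino acid (0.0546), antioxidant (0.0546), endothelial (0.107) and transport calls (0.0663) ended. With the prefix number the antioxidant (0.0709), endothelial (0.290), cell cycle (0.0709) and transport calls (0.0709) did. The decidua score ended the antioxidant (0.0826) and cell cycle calls (0.192). Both tissue scores ended the antioxidant (0.0911), cell cycle (0.211) and amino acid calls (0.0709), and upper-quartile factors the transport call (0.0517). Lists called in no stress comparison included, in the averaged effect, the unfolded protein response (0.215), hypoxia response (0.453), serotonin and tryptophan handling (0.788, 1 gene higher adjusted over the list alone), steroid hormone synthesis (0.788), the insulin-like growth factor axis (0.788), labyrinth trophoblast progenitors (0.798), stroma and pericytes (0.449, 1 gene higher adjusted over the list alone), uterine natural killer cells (1 gene lower adjusted over the list alone), cytosolic ribosomal proteins (0.0686) and X-linked escape genes (0.215).

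**Figure D3:**
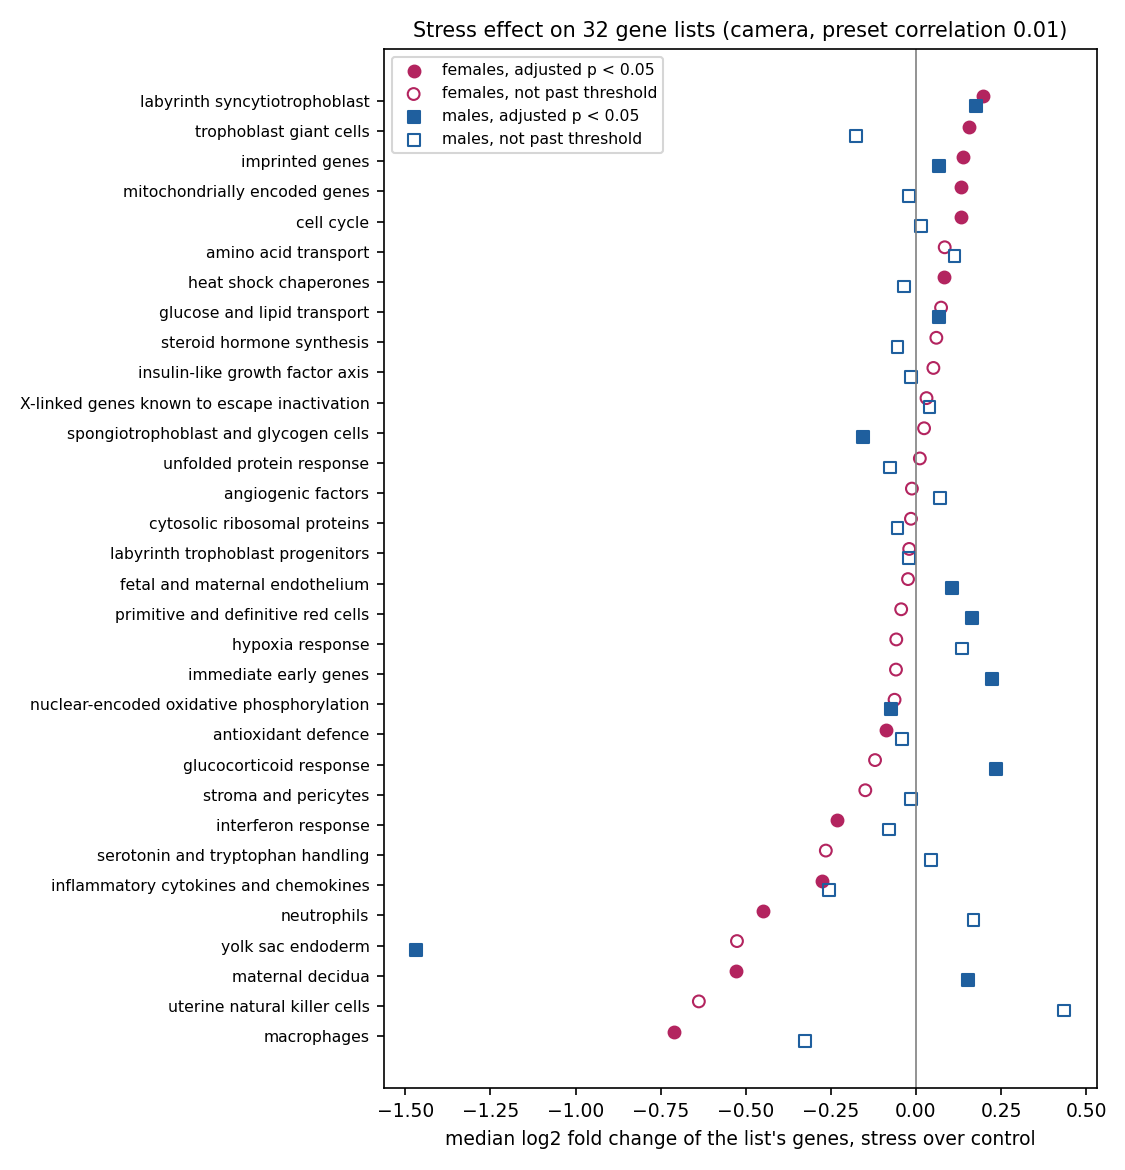
Median log2 fold change (horizontal axis) of the genes of each list in females and in males, stress against control, for the lists named along the vertical axis, with filled markers for lists with a camera adjusted p under 0.05 at the preset correlation. The decidua list lay at -0.53 in females and 0.15 in males, and the syncytiotrophoblast list at 0.20 and 0.18.

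For the averaged effect edgeR called 0 genes (smallest adjusted p 0.103), with 1848 at an unadjusted p under 0.05 (883 higher, 965 lower), and DESeq2 called 112 (59 higher, 53 lower). Genes higher with the smallest p were Ankrd23 (0.52 ± 0.10), Syna, Fbxo38 (0.14 ± 0.03), Lgals8, a galectin (0.24 ± 0.05), and Tbc1d14 (0.21 ± 0.04). Lower were Hsd17b10, a mitochondrial dehydrogenase (-0.24 ± 0.05), the potassium channel Kcnj12 (-0.52 ± 0.10), Cyb5r1 (-0.35 ± 0.07), Zfp994 (-0.49 ± 0.10) and Iqcg (-1.18 ± 0.27). Leaving out male control replicate 3, male control replicate 5 or female stress replicate 2 gave 2, 3 and 1 calls in place of 0, and both tissue scores as covariates gave 3 (2 higher, 1 lower). Fixed genes lay between -0.60 ± 0.59 (Tph1) and 0.26 ± 0.31 (Hsd11b1).

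Stress effects in the sexes were set side by side across genes, which are not independent replicates. Pearson's r across the 14848 genes was 0.27 and Spearman's rho 0.187, with 57.8% of genes in the same direction. Among the 2357 genes with an unadjusted p under 0.05 in either sex r was 0.379, rho 0.387 and 70.7% had the same direction. On differences of mean log2 CPM r was 0.0746. When the stress labels were moved among library-name prefixes, 64 of 100 draws gave an r at least as high on that measure, while the r of the fitted fold changes was not set against moved labels.

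Female and male placentas of control dams were compared to see which genes the sexes differed in without stress. As a check of the labels, the Y-linked genes Ddx3y, Kdm5d and Uty had 0 TPM in all 12 female libraries. In the 12 male libraries Ddx3y had 20.8 ± 1.98 TPM (SD), Kdm5d at least 1.16 and Uty at least 2.48, and Eif2s3y had 23.6 ± 4.18 against at most 0.243 in females. Beyond these, 5 X-linked genes were higher in females. Taf1 (ENSMUSG00000031314, chromosome X, 101532734 to 101601789 on GRCm38, protein-coding), a subunit of the general transcription factor TFIID, had 46.0 ± 3.69 CPM in female and 31.2 ± 2.66 in male controls (SD, n = 6), a log2 difference of 0.56 ± 0.06 (edgeR adjusted p = 8.26e-05). Eif2s3x (ENSMUSG00000035150, chromosome X, 94188707 to 94212862), of translation initiation, had 238 ± 19.4 and 174 ± 6.70 CPM (0.45 ± 0.05, adjusted p = 0.000162). The histone demethylases Kdm5c (ENSMUSG00000025332, chromosome X, 152233020 to 152274535; 0.36 ± 0.06, adjusted p = 0.0177) and Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936; 0.34 ± 0.06, adjusted p = 0.0183) were higher too, as was the prolyl isomerase Pin4 (ENSMUSG00000079480, chromosome X, 102119447 to 102127669; 0.65 ± 0.11, adjusted p = 0.0177). Eif2s3x, Kdm5c and Kdm6a have close homologues on the Y chromosome, so reads shared by a pair could be counted for either gene. The 1 autosomal gene called was Uba5 (ENSMUSG00000032557, chromosome 9, 104046599 to 104063134), the activating enzyme of ufmylation, lower in females at 68.9 ± 8.98 against 101 ± 10.3 CPM (-0.55 ± 0.07, adjusted p = 0.000730). All 6 female libraries lay above all 6 male ones for Taf1, Eif2s3x, Kdm5c, Pin4 and Kdm6a, and below them for Uba5.

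**Figure D4:**
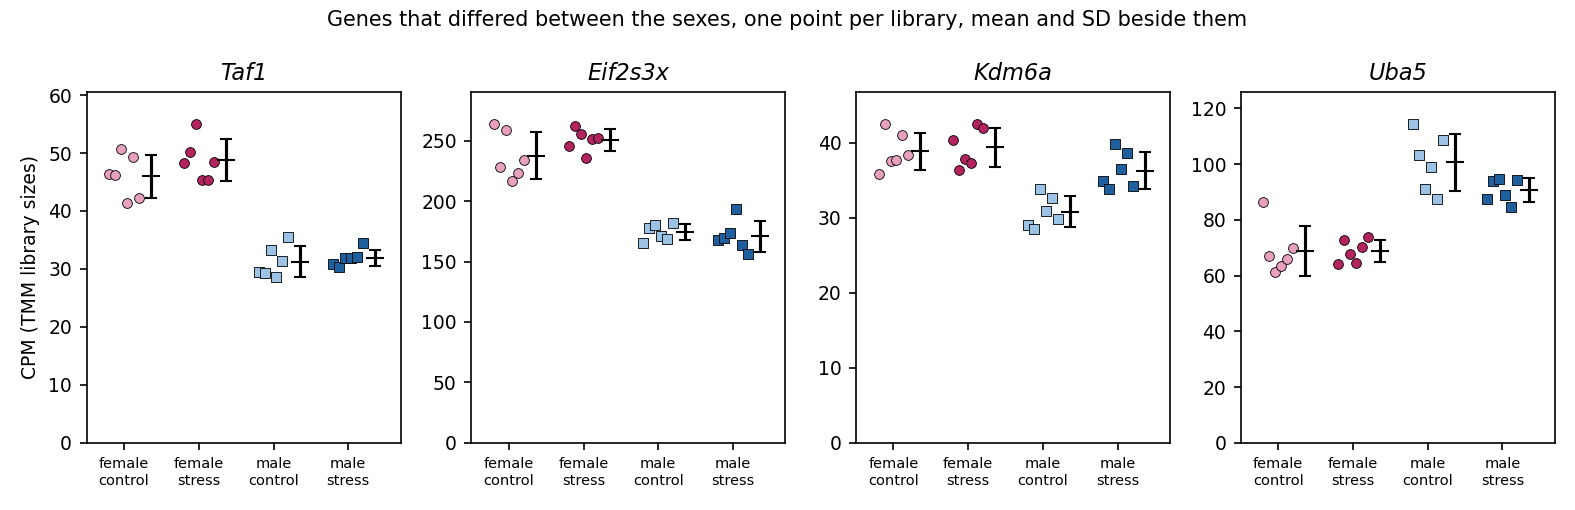
CPM (vertical axis) of Taf1, Eif2s3x, Kdm6a and Uba5 in each library, by group, with bars at the mean and SD of 6 libraries. Taf1 had means of 46.0 and 48.8 CPM in control and stressed females and 31.2 and 31.9 CPM in control and stressed males.

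In total edgeR called 6 genes in controls (5 higher and 1 lower in females, 671 at an unadjusted p under 0.05) and DESeq2 10, with all 6 among them. The genes of the Y-linked list and Xist were absent from the count table, so they could not be among these calls. The X-linked list of genes known to escape inactivation was higher in 8 of 9 cases (adjusted p = 6.43e-15, and 0.000175 with an estimated correlation), with 3 genes called over all genes and 4 adjusted over the list alone, where Utp14a (0.31 ± 0.08) joined. Leaving out female control replicate 5 or male control replicate 1 or 5 ended the Kdm5c call (adjusted p = 0.0747, 0.0708 and 0.0621), leaving out male control replicate 2, 3 or 4 that of Pin4 (0.0618, 0.0503 and 0.0584), and leaving out female control replicate 2 or 5 or male control replicate 1, 2, 4 or 6 that of Kdm6a (0.0584 to 0.0856). Without the 4 deep control libraries the 3 calls ended too (0.158, 0.164 and 0.284). With the library-name prefix as a block 4 of the 6 calls ended, those of Eif2s3x (0.0883), Kdm5c (0.0883), Pin4 (0.150) and Kdm6a (0.478). With only the compared groups in the fit 4 ended as well, those of Uba5 (0.196), Kdm5c (0.479), Pin4 (0.479) and Kdm6a (0.462). The Kdm5c call also ended with voom weights (0.0611) and without the 3 low-decidua libraries (0.121), and that of Kdm6a without those libraries (0.0581) and on log2(TPM + 1) and log2(TPM + 0.1) (0.309 and 0.293). Other values lower in females were those of Krt5 (-5.543 ± 1.504, from 1 male control library with 46.9 CPM), Parp1 (-0.21 ± 0.06), Zfp709 (-0.38 ± 0.11) and Vgf (-0.54 ± 0.17).

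In controls 3 of the 4 trophoblast lists also differed between the sexes. Spongiotrophoblast and glycogen cell markers were lower in females in 21 of 22 cases (median -0.22, adjusted p = 2.55e-07), with Prl6a1, a placental prolactin, at -0.55 ± 0.25 (SE, n = 6 per group). Syncytiotrophoblast markers were higher in 19 of 20 cases (3.17e-07), with Glis1, a zinc finger factor, at 0.37 ± 0.11. Unfolded protein response genes were lower in 17 of 19 cases (2.27e-06), with the chaperone Hspa5 at -0.24 ± 0.13, and endothelial markers higher in 16 of 17 (0.000221, Tie1 0.23 ± 0.10). The adjusted p of these 4 lists with an estimated correlation was 0.405, 0.405, 0.415 and 0.448. Yolk sac markers were lower in 21 of 21 cases (0.000976, Dab2 -0.39 ± 0.39), giant cell markers in 12 of 17 (0.00760, Prl2c5 -0.41 ± 0.19) and mitochondrially encoded genes in 12 of 13 (0.0390, mt-Nd3 -0.53 ± 0.29). Glucose and lipid transport genes were higher in 16 of 21 (0.0108), where the lipase Lipg (0.31 ± 0.08) passed adjusted over the list alone, angiogenic factors in 17 of 20 (0.0461, Vegfb 0.21 ± 0.11) and amino acid transporters in 13 of 18 (0.0461, Slc16a10 0.27 ± 0.10), the last with a mean just below 0 (-0.00281). With an estimated correlation the adjusted p of these 6 lists was 0.405 to 0.840. Apart from the X-linked list and Lipg, 0 genes of the called lists passed over all genes or adjusted over the list alone. Without single libraries these calls ended: yolk sac (female control replicates 1 and 3 and male control replicates 1 and 5, 0.0573 to 0.399), giant cells (female control replicates 2 and 6 and male control replicates 2 and 6, 0.0607 to 0.143), mitochondrial genes (female control replicate 1 and male control replicates 2 and 3, 0.145 to 0.820), glucose and lipid transport (female control replicate 4 and male control replicate 6, 0.0558 and 0.0862), angiogenic factors (female control replicates 2, 4, 5 and 6 and male control replicates 2, 3 and 6, 0.0821 to 0.355) and amino acid transport (female control replicates 1, 2, 3 and 5 and male control replicates 1, 2, 5 and 6, 0.0565 to 0.167). The mitochondrial call ended in 6 of 9 other settings, among them the decidua score (0.0533), the yolk sac score (0.0526), both (0.0758), the prefix number (0.0581) and the loss of the 4 deep control libraries (0.744). Yolk sac markers lost the call with the yolk sac score (0.836), both scores (0.860) and without the 3 low-decidua libraries (0.0727). Angiogenic factors lost it with the decidua score (0.145), both scores (0.101) and relative log expression factors (0.0533), and amino acid transporters did with the yolk sac score (0.0690), without the low-decidua libraries (0.137) and without the deep ones (0.0812).

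The same question was asked of stressed placentas. Taf1 had 48.8 ± 3.61 CPM in stressed females and 31.9 ± 1.43 in stressed males (0.61 ± 0.06, edgeR adjusted p = 7.87e-06), and Eif2s3x 251 ± 9.06 and 171 ± 12.7 (0.55 ± 0.05, adjusted p = 6.70e-06). Acat1 (ENSMUSG00000032047, chromosome 9, 53580522 to 53610382), a mitochondrial thiolase of ketone body and isoleucine breakdown, had 107 ± 9.27 and 84.6 ± 5.51 CPM (0.34 ± 0.06, adjusted p = 0.0214), against 102 ± 5.27 and 90.7 ± 5.44 in controls. These 3 were the genes edgeR called, with 1590 at an unadjusted p under 0.05 (654 higher, 936 lower), and DESeq2 called 11 with all 3 among them. Uba5 had 68.8 ± 4.08 CPM in females and 90.6 ± 4.28 in males (-0.40 ± 0.07) and Kdm5c 272 ± 6.27 and 216 ± 15.3 (0.33 ± 0.06), both at an adjusted p of 0.0520. The Acat1 call ended without any 1 of female stress replicates 2, 5 and 6 and male stress replicates 1, 3, 4 and 5 (0.0643 to 0.110) with the decidua score (0.465) or both tissue scores (0.425) as covariates, without the 3 low-decidua libraries (0.194) and with only the compared groups in the fit (0.146). Other genes lower in females by value were Poglut1 (-0.31 ± 0.07), the calcium channel Orai2 (-0.91 ± 0.21), Eps8l1 (-0.70 ± 0.16) and the adrenergic receptor Adrb2 (-1.47 ± 0.36).

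Decidua markers were lower in stressed females than in stressed males, in 18 of 20 cases with a median of -0.64 (adjusted p = 1.08e-09). Esr1 had -0.90 ± 0.30 and Hand2, a transcription factor of the decidua, -0.98 ± 0.42. Glucocorticoid response genes were lower in 16 of 21 cases (1.78e-05), with Sgk1 at -0.73 ± 0.26 and Errfi1 at -0.51 ± 0.19. Both lists had an adjusted p of 0.304 with an estimated correlation. The X-linked escape list was higher in 9 of 9 cases (7.86e-08, and 0.00920 with an estimated correlation), with 1 gene called over all genes and 2 adjusted over the list alone. Syncytiotrophoblast markers were higher in 17 of 20 cases (0.000460, Gcgr 0.35 ± 0.14), imprinted genes in 24 of 31 (0.0380, Cdkn1c 0.32 ± 0.11), cell cycle genes in 23 of 25 (0.0289, Ccnb2 0.24 ± 0.14) and giant cell markers in 15 of 17 (0.0442, Hand1 0.18 ± 0.13). Lower in stressed females were uterine natural killer cell markers, in 11 of 12 cases (0.000696, Itga1 -0.25 ± 0.11), macrophage markers in 13 of 17 (0.00439, Cd68 -0.69 ± 0.25), unfolded protein response genes in 17 of 19 (0.0277, Chac1 -0.99 ± 0.40), hypoxia response genes in 13 of 19 (0.0289, Bnip3 -0.58 ± 0.21), neutrophil markers in 9 of 11 (0.0289, Ltf -1.66 ± 0.69) and immediate early genes in 14 of 17 (0.0321, Ier3 -0.56 ± 0.24). With an estimated correlation the adjusted p of these 10 lists was 0.520 to 0.690, and 0 of their genes passed over all genes or adjusted over the list alone. With the decidua score as a covariate 12 of the 13 calls ended (0.0527 to 0.554), among them decidua (0.412), glucocorticoid response (0.261) and syncytiotrophoblast genes (0.0718). With both tissue scores 11 ended (0.0987 to 0.388), and without the 3 low-decidua libraries 7 did (0.0874 to 0.274), those of uterine natural killer cell, macrophage, neutrophil, hypoxia, immediate early, imprinted and giant cell genes. Calls that ended without single libraries were those of cell cycle genes (female stress replicates 1, 3 and 6 and male stress replicates 2, 5 and 6, 0.0559 to 0.273), imprinted genes (female stress replicates 3, 4 and 6 and male stress replicates 1 and 2, 0.0571 to 0.126), giant cell markers (female stress replicates 3, 4 and 6 and male stress replicates 2, 4 and 6, 0.0632 to 0.149), unfolded protein response (female stress replicates 1 and 3 and male stress replicates 2 and 6, 0.0632 to 0.0922), hypoxia (female stress replicates 3 and 5, 0.0571 and 0.0701), immediate early (female stress replicates 1 and 5 and male stress replicate 2, 0.0658 to 0.251) and neutrophil genes (female stress replicate 5, 0.104).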

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

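The tests on random splits of the libraries and the alternatives with the yolk sac score, the left-out low-decidua libraries and the left-out deep control libraries were chosen only after the results they bear on were seen. Each set of 100 splits included the real grouping, so every count of splits below holds it. Highest counts and smallest other p-values leave it out. For the averaged effect labels were moved within each sex, which parts libraries of a shared prefix, so its counts of splits may be too small. For the difference and the sex comparisons labels were moved within each treatment. In the real grouping 11 of the 13 prefixes had a library of each sex. Random splits need not keep this balance, so the counts of splits for these comparisons may be too large. For the 3 patterns below, predictions for the tests with covariates or left-out libraries were written before their values. Related list tests under the same covariates and left-out libraries had been seen by then. Predictions for the random splits were written after.

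Lists whose stress effect differed between the sexes by the interaction test were maternal decidua (mean log2 fold change in females minus males -0.67), neutrophils (-0.74), glucocorticoid response (-0.40), angiogenic factors (-0.20), interferon response (-0.16), fetal and maternal endothelium (-0.14), heat shock chaperones (0.0571), cell cycle (0.11), spongiotrophoblast and glycogen cells (0.18), trophoblast giant cells (0.29) and yolk sac endoderm (0.90). With an estimated correlation 0 of these 11 lists were called (smallest adjusted p 0.473). In random splits of the libraries 38 of 100 called at least as many lists for this difference as the real 11, with a highest count of 18, so chance cannot be excluded for the number of lists.

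Single libraries far from the other 5 of their group were found in 24 of 260 groups tested, against 13 for chance, which flags about 1 in 20 groups. Male stress replicate 2 had 42.8 M counts (others 19.5 to 24.7) and an Igf2 of 2441.5 CPM (2665 to 2797), and female control replicate 3 a decidua score of 4.63 (5.61 to 5.82) and a Slc6a4 of 11.6 CPM (3.60 to 5.62). In CPM, female control replicate 1 stood out for Pin4 (13.1, others 8.06 to 8.96), Uba5 (86.3, others 61.3 to 69.9) and Slc38a4 (2356, others 886 to 1342), and female control replicate 6 for Acad10 (16.5, others 11.9 to 13.6). Among male controls, replicate 1 stood out for Krt5 (46.9, others 0.0737 to 1.08), C1ql1 (3.10, others 0.884 to 1.45) and Adrb2 (2.37, others 0.825 to 1.33), replicate 3 for Hsd11b2 (266.8, others 145 to 188), replicate 4 for Pla2g6 (79.6, others 72.6 to 75.1) and replicate 5 for Acad10 (19.6, others 12.2 to 14.7) and Vegfa (84.6, others 52.0 to 63.2). Among stressed females, replicate 2 stood out for Kcnj12 (9.47, others 5.19 to 5.49) and Eps8l1 (3.06, others 1.63 to 2.14), replicate 3 for Brd3os (1.73, others 2.34 to 2.69) and replicate 5 for Ankrd23 (22.7, others 16.6 to 18.5) and Krt5 (1.48, others 0 to 0.204). Among stressed males, replicate 5 stood out for Foxj3 (64.7, others 54.4 to 57.9) and Poglut1 (29.8, others 24.6 to 26.2), and replicate 6 for Syna (218.9, others 153 to 177) and Eps8l1 (4.00, others 3.13 to 3.39).

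The first pattern weighed was the lower decidua, interferon, cytokine, macrophage and neutrophil lists in stressed females. The mean score of the 4 immune lists differed by -0.55 (95% interval -0.95 to -0.16), and by -0.27 (-0.62 to 0.08) with the decidua score in the model. That is under 50% of its size by a narrow margin, as less decidua in these libraries would need. The interferon and macrophage lists kept their calls in 9 of 9 other settings at the preset correlation, the decidua score among them. Such a kept call cannot decide the question for these 2 lists. With an estimated correlation neither was called (camera adjusted p = 0.378 and 0.440). The decidua difference was -0.65 with the 3 libraries with little decidua and -0.36 (-0.71 to -0.01) without them, so it kept at least 50% of its size. These libraries were picked by the score tested itself, and female control replicate 3 is among them. Leaving that control out raises the control mean, so the test cannot exclude a few libraries as the cause. A decidua camera p as small came up in 4 of 100 random splits (real 2.24e-08, smallest other 1.81e-12), an interferon one in 11 (real 3.11e-07, smallest other 4.64e-10), a macrophage one in 12 (real 1.83e-05, smallest other 2.11e-10), a cytokine one in 6 (real 0.000306, smallest other 3.76e-05) and a neutrophil one in 7 (real 0.00336, smallest other 1.20e-05), so chance cannot be excluded for the last 4, and for the decidua list it is not set aside either, with 2 lists under 5 splits in females against 1.28 for chance and an exact permutation p of 0.0996 for its score. Whether restraint changed the decidua itself or the share of it in the dissected tissue stays open and was not tested.

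Higher syncytiotrophoblast markers in stressed libraries of both sexes were weighed next. Their score differed by 0.20 (0.06 to 0.34), and by 0.18 (0.06 to 0.29) with the yolk sac and decidua scores in the model. A smaller share of these tissues, as far as the scores measure it, is thus not the whole cause. Without the 4 deep control libraries the syncytiotrophoblast score differed by 0.11 (-0.02 to 0.23), an interval that spans 0 and does not decide. The list kept its call in 9 of 9 other settings at the preset correlation, this one among them. A camera p as small came up in 2 of 100 random splits (real 6.69e-11, smallest other 1.16e-12), and 2 of 32 lists had under 5 such splits against 1.28 for chance. Because these splits parted libraries of a shared prefix, the 2 of 100 may come out too small. Within 1 sex, a camera p as small came up in 14 of 100 splits in females (real 1.83e-06) and 8 of 100 in males (real 6.02e-08). Chance therefore cannot be excluded within either sex. An effect of stress on the labyrinth stays open and was not tested.

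Higher glucocorticoid response genes in stressed males were the last pattern. Their score differed by 0.26 (-0.06 to 0.59), and by 0.18 (0.05 to 0.31) with both tissue scores in the model. More decidua, whose score was higher by 0.19 in these males, did not account for the whole difference as far as these scores measure it. The scores only stand in for the share of a tissue, and the difference without them could not be told from 0. More decidua is therefore not excluded. The yolk sac score of these males was lower by 0.92, so more yolk sac was never in question. Without the 4 deep control libraries the glucocorticoid score differed by 0.27 (-0.13 to 0.67), no smaller. Its interval spanned 0 with and without these libraries, so the score does not decide whether they are the whole cause. The list kept its call in 9 of 9 other settings at the preset correlation, the loss of these libraries among them. That does not decide either, since the list was not called with an estimated correlation (camera adjusted p = 0.692). A camera p as small came up in 1 of 100 splits, that of the real grouping itself (real 1.91e-06, smallest other 5.43e-06). Among 32 lists about 1.28 would pass under 5 such splits by chance, so the glucocorticoid list in males remains a hypothesis found in the same data, with an effect of maternal hormone open and not tested.

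In counts of called genes, the real count and the highest of 100 random splits were 0 and 172 for stress in females, 0 and 1 in males, 0 and 255 for the difference between sexes, 0 and 12 averaged over the sexes, 6 and 1054 for the sexes in controls and 3 and 3 for the sexes under stress. A real count of 0 is reached by 100 of 100 splits, while 8 splits reached 6 in controls and 2 reached 3 under stress, the real grouping among them each time. The split with 1054 calls parted the libraries by yolk sac score (a difference of 4.24, against -1.14 between the real groups), which points to a structure of the samples. That with 172 held a decidua score difference of 0.888 and both deep female libraries on the same side, which cannot be told apart, and that with 255 held a yolk sac contrast of -2.46. For genes at an unadjusted p under 0.05 the counts were 1362 in females (reached by 12 splits, highest 2958), 1150 in males (4, highest 1977), 635 for the difference (50, highest 2353), 1848 averaged (4, highest 3068), 671 for the sexes in controls (68, highest 3237) and 1590 under stress (2, highest 1785). For lists called they were 12 in females (31, highest 18), 11 in males (22, highest 16), 11 averaged (43, highest 18), 11 in controls (54, highest 21) and 13 under stress (7, highest 16), so chance cannot be excluded for any of these 5 numbers of lists. The other splits called a median of 10 lists in females, 8 in males and 10 for the difference. Their median was 10 averaged, 11 in controls and 7 under stress. For single called lists, a camera p as small came up in 1 to 45 splits for the difference and 2 to 54 averaged. It came up in 1 to 53 splits for the sexes in controls and 2 to 42 under stress.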

How the results depend on the processing

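The settings with the yolk sac score, both tissue scores, the prefix number, left-out low-decidua libraries, left-out deep control libraries and single libraries left out of the list tests were chosen only after the results were seen. Of 360 counts of calls and correlations between the sexes under an alternative 319 stayed the same, which for a count meant within 1.5 times the reported one. Of 1782 list calls 1436 kept direction and side of the threshold, 333 kept the direction alone and 13 turned. For named genes and library list scores 3471 of 3634 values were the same, 41 lost and 48 gained a call, 74 moved and 0 turned.

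DESeq2 called 12 genes for stress in females, 8 in males, 1 for the difference between sexes, 112 averaged over the sexes, 10 for the sexes in controls and 11 under stress. The averaged stress effect had 28 calls with the replicate number as a block, 3 with both tissue scores, and 0 to 3 without single libraries. The other settings kept 0 calls for stress in females, in males and for the difference, with 0 without any single library. In controls the sex difference had 3 calls without the 4 deep libraries, 2 with only the 2 groups compared, 2 with the prefix as a block, and 4 to 9 without single libraries. Under stress it had 5 with relative log expression factors, 6 with upper-quartile factors, 5 with no filter, 5 with the stricter filter, 7 with voom weights, 9 with log2(TPM + 1), 9 with log2(TPM + 0.1), 5 with the yolk sac score, 6 without the deep libraries, 7 with only the 2 groups compared, 5 with the prefix as a block, and 2 to 4 without single libraries. In each of these counts the cause was not tested.

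With an estimated correlation the lists called were 0 in females, 0 in males, 0 for the difference, 0 averaged, 1 for the sexes in controls and 1 under stress, because that correlation widens the error of a list whose genes vary together. Males had 17 with the replicate block, the difference 7 with the yolk sac score and the averaged effect 7 without the deep libraries. Under stress the sexes differed in 4 with the decidua score, 5 with both scores and 6 without the low-decidua libraries. Without single libraries the ranges were 10 to 15 in females, 6 to 15 in males (6 without male control replicate 6), 6 to 15 for the difference (6 without male control replicate 1), 8 to 14 averaged, 7 to 14 in controls and 8 to 17 under stress. Directions turned for yolk sac in males with the yolk sac score (adjusted p = 0.799) and both scores (0.771), for interferon (0.967) and cell cycle genes (0.894) in the difference with both scores, for angiogenic factors there with the decidua score (0.749) and both scores (0.947), and for endothelium in the averaged effect without the deep libraries (0.990). Under stress they turned with the decidua score and both scores for immediate early genes (0.355 and 0.388), uterine natural killer cells (0.261 and 0.364) and cell cycle genes (0.554 and 0.388). A score holding a list's own genes removes that list by construction, and for the others the cause was not tested.

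Deviations of libraries sharing a replicate number correlated from -0.39 to 0.06 between the sexes in controls, -0.14 to 0.29 under stress (5 of 6 over 0.1), -0.36 to -0.03 between stress and control females and -0.29 to 0.30 in males, so not every pair matched. By prefix, pairs in controls ran from -0.39 to 0.61, with 2 of 5 over 0.1 (0.491 and 0.609) and 3 matching best with their own prefix, and under stress from -0.14 to 0.29, with 5 of 6 over 0.1 and 2 matching best. The consensus correlation by prefix was 0.135, a likeness that the reported p-values do not take into account. With the replicate block the heat shock list in females (0.0632), the mitochondrial list (0.0528) and Pin4 (0.0560) in controls and Acat1 under stress (0.106) were not called. The largest shift of all log2 fold changes by another scaling was 0.0152. With 18.3 M counts in the smallest library, changes in genes near 1 CPM rest on about 18.3 counts there.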

Other observations

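Genes in this part were chosen only after their values were seen. The enzymes that add and remove the sugar O-GlcNAc on proteins both had higher means in females. Mgea5, the autosomal gene of the enzyme that removes it (also named Oga), had 99.6 ± 6.02 CPM in control and 99.4 ± 8.66 in stressed females (SD, n = 6) and 79.0 ± 7.20 and 80.0 ± 5.88 in males. Its sex difference was 0.34 ± 0.07 in controls (adjusted p = 0.0714) and 0.31 ± 0.07 under stress (adjusted p = 0.164), so edgeR called it in neither, while DESeq2 called it in both. The X-linked transferase Ogt, a marker of maternal stress in earlier placenta work, had 86.0 ± 16.5 and 89.1 ± 10.3 CPM in control and stressed females and 72.5 ± 7.51 and 74.5 ± 9.09 in males, with stress effects of 0.05 ± 0.11 and 0.04 ± 0.11.

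The sex difference in Uba5 was also seen at the level of its main transcript, which had 43.3 ± 2.70 TPM (40.2 to 47.8) in 12 female and 59.0 ± 4.82 TPM (53.0 to 69.5) in 12 male libraries (SD). Ceacam2, a cell adhesion gene of a family with close copies, reached at most 0.0737 CPM in the 12 stressed libraries, and had means of 0.947 ± 0.980 CPM in female and 0.696 ± 0.897 in male controls, where 5 of 12 libraries had at least 1 CPM. Rpl21, a ribosomal protein gene with many copies, had 145 ± 51.7 and 244 ± 49.2 CPM in control and stressed females and 156 ± 42.998 and 244 ± 52.5 in males. Its values also differed by library-name prefix within each treatment, and the treatments overlapped. Controls had 88.8 to 116 CPM for N1 and N2 and 121 to 238 for N3 to N8. Stressed libraries had 167 to 189 CPM for R1 and R3 and 260 to 295 for R6 to R9. Afp had group means of 2754 ± 4486 CPM in control and 1822 ± 1675 in stressed females and of 4983 ± 6290 and 1505 ± 1481 in males (SD).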
